A study of Mus musculus with 8 samples.

How the data were processed

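Sorted LSK cells of 4 db/m and 4 db/db samples were profiled by RNA-seq. Per the labels' protocols the cells were sorted by flow cytometry, RNA was isolated with Trizol and libraries were made with an ultralow-input mRNA method. The deposited project sheet records 1 lane of a sequencer for all 8 libraries. Reads were mapped with STAR 2.7.10a to mm10 and counted per gene with featureCounts of Subread 2.0.3, per the submitters' processing notes, which also name FastQC 0.11.5 and edgeR 3.40.2. The annotation and the strand setting of the counting are not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart, and members of gene families such as Ly6 may share reads.

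The authors deposited raw read counts for 13708 genes, and the smallest row total was 79, so a filter that no source states had been applied before deposit. Beside the counts the authors deposited log2 CPM values, which match TMM-scaled log2 CPM computed here with a prior count of 2 to within 4.97e-14. The authors' deposited p-values and log2 fold changes match edgeR's likelihood ratio test. The deposited mapping table gave reads per region, from which shares were computed as percent of uniquely mapped reads, and the RNA integrity number is a score that the deposited project sheet records per sample. In 21 rows the symbol had become a date, and these rows were tested under their position. At least 99.9% of the reads mapped on genes were in the table in each library.

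Counts were analysed in R 4.3.3 with edgeR 4.0.16 by TMM scaling, the filterByExpr rule, which removed no gene, and the quasi-likelihood test of db/db against db/m, with Benjamini-Hochberg adjustment and a threshold of 0.05. No covariate was used. CPM values are scaled by TMM and given as mean ± SD of 4 libraries, and SE is that of the log2 fold change. The biological coefficient of variation was 31.3%. Correlations of log2 CPM between libraries ran from 0.933 to 0.976, and no pair agreed within sampling noise (lowest chi-square per gene 48.2), so each library counted once.

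Gene lists fixed before the data were examined numbered 37, and 36 with at least 3 tested genes were tested with camera at a preset correlation of 0.01; the mitochondrially encoded list was not analysed here. Each was also tested with an estimated correlation and with fry. The genes near Lepr were compared by Fisher's exact test and library measures by exact permutation. A plasma cell list of 16 genes and its subset of 7 identity genes were added after the data were seen. Genes named are Lepr, the called genes with non-overlapping groups and an average log2 CPM of at least 2 (up to 12 per direction), the 3 of smallest p per direction, up to 4 members of smallest p per described list and the Y-linked genes. Members outside this rule, Kit, Jchain and the members named from lists that were not called among them, were chosen after their values were seen.

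On simulated counts for this comparison, with 200 genes changed, the quasi-likelihood test recovered 49% of 2-fold and 90.9% of 4-fold changes with 4.79% false calls among 13642 genes. The likelihood ratio test recovered 61% and 96.0% with 20.4% false calls, and DESeq2 had 23.1% false calls. Of 20 unchanged lists 0 were called, in a simulation that holds no correlation between genes. Alternatives fixed in advance were RLE and upper-quartile scaling, no filter and a stricter one of at least 1 CPM in 4 libraries, DESeq2, limma-voom with and without quality weights, the title prefix as a correlated block, 1 surrogate variable and the omission of each library. Added later were the likelihood ratio test, the plasma cell level as a covariate and 2 sets of omitted libraries. The 4 title prefixes each occur in 1 genotype, so a difference between prefixes cannot be told apart from genotype in full.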

Results

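Messenger RNA was sequenced from LSK cells, the lineage-negative, Sca-1-positive, c-Kit-positive fraction of mouse bone marrow that holds the stem and multipotent progenitor cells of blood. The libraries came from 4 samples of db/m mice, which are heterozygous for the mutated leptin receptor, and 4 samples of db/db mice, which are homozygous for it and become obese and diabetic. All 8 samples were labelled as taken 6 months after diabetes. The genotype label set the groups, because all 8 sample titles carry the db/m name, including those of the homozygous samples. The counts assigned to genes came to between 27640853 and 42806327 per library, and levels are given as CPM, counts scaled to a common library total. The labels do not state that each library came from a separate mouse, so the p-values measure the spread between these samples.

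The comparison of db/db with db/m asked which transcripts differ in these cells after long-standing diabetes. Ly6a, which encodes the Sca-1 antigen used to sort LSK cells, fell from 466 ± 115 CPM in db/m to 131 ± 36.1 CPM in db/db (SD, n = 4 each), a log2 fold change of -1.83 ± 0.24 (SE). Ckap4, a membrane protein of the rough endoplasmic reticulum, fell from 155 ± 33.2 to 60.8 ± 9.12 CPM, and Cnp, a phosphodiesterase best known from myelin, fell from 182 ± 6.03 to 108 ± 6.27 CPM. Pde3b, the phosphodiesterase that lowers cyclic AMP downstream of insulin, rose from 28.2 ± 4.77 to 67.5 ± 8.07 CPM, and Klhl4, a kelch-like protein, rose from 25.1 ± 2.91 to 58.7 ± 10.7 CPM. In each of these genes all 4 db/db libraries lay on one side of all 4 db/m libraries.

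**Figure D1:**
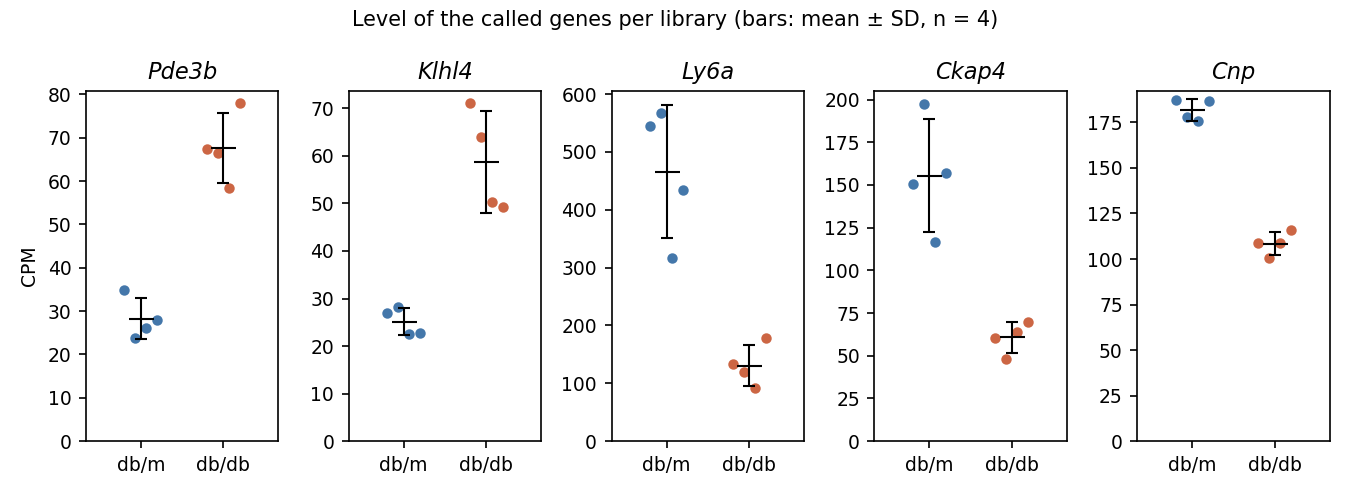
Normalised level (CPM, linear axis from 0) of the 5 genes that passed the test, in each of 4 db/m and 4 db/db libraries; points are libraries, and bars give the mean ± SD. The groups do not overlap for any of the 5 genes, with Ly6a at 466 CPM in db/m and 131 CPM in db/db.

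These 5 genes, 2 higher and 3 lower in db/db, were all that passed an adjusted p of 0.05 among 13708 genes tested, each with an adjusted p of 0.0445 by edgeR's quasi-likelihood test. Log2 fold changes were 1.26 ± 0.15 for Pde3b, 1.22 ± 0.16 for Klhl4, -1.36 ± 0.17 for Ckap4 and -0.75 ± 0.09 for Cnp (SE). In mm10, Ly6a lies on chromosome 15 from 74994877 to 74998031, Pde3b on chromosome 7 from 114415254 to 114537937, Klhl4 on chromosome X from 114474333 to 114561129, Ckap4 on chromosome 10 from 84526305 to 84533888 and Cnp on chromosome 11 from 100574939 to 100581739. Zan, the next gene by p in the upward direction, had 4.91 ± 0.254 CPM in db/m and 12.01 ± 1.40 CPM in db/db, with an adjusted p of 0.0740 that missed the threshold. At an unadjusted p under 0.05, 2100 genes (15.3% of those tested) stood out, 1067 higher and 1033 lower, and at an adjusted p under 0.1 there were 223, 93 higher and 130 lower. The groups did not overlap in 1238 genes, 9.03% of those tested, where chance gives 2.86%. The authors' deposited table lists 587 genes with a false discovery rate under 0.05, 285 higher and 302 lower, and its p-values match edgeR's likelihood ratio test to within 1.28e-09. Under limma-voom and upper-quartile scaling all 5 missed the threshold, with adjusted p of 0.0566 to 0.0586 and log2 fold changes close to those above (Ly6a -1.85 and -1.81, Pde3b 1.25 and 1.28). The 5 calls also ended with the plasma cell level as a covariate (described with the secretory genes), with adjusted p of 0.217 to 0.397. There the log2 fold changes were 1.42 for Pde3b, 1.06 for Klhl4, -1.17 for Ly6a, -0.75 for Ckap4 and -0.62 for Cnp. Without 1 library the count was 0 (db/m replicate 2 or 4, or db/db replicate 1, 2 or 3), 2 (db/m replicate 1), 46 (db/db replicate 4) or 90 (db/m replicate 3). In the 5 fits with 0 calls the log2 fold changes of these genes stayed about as large (Ly6a -1.87 to -1.70, Ckap4 -1.38 to -1.22, Cnp -0.76 to -0.71, Pde3b 1.19 to 1.32, Klhl4 1.12 to 1.29), with adjusted p of 0.0615 to 0.184.

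Genes of platelet-forming and red cell lineages were higher in db/db. All 14 tested megakaryocyte genes had positive log2 fold changes, with a median of 1.29, and 9 of them rose when adjusted over the list alone (0 over all genes). Pf4, a chemokine stored in platelet granules, went from 104 ± 36.6 to 381 ± 173 CPM, Itga2b, the platelet integrin CD41, from 184 ± 29.6 to 431 ± 138 CPM, and Gp9, part of the von Willebrand factor receptor, from 15.7 ± 5.52 to 42.02 ± 9.73 CPM. All 14 tested erythroid genes were also positive, with a median log2 fold change of 2.03, and 13 rose adjusted over the list alone (0 over all genes). Among them were Car2, a carbonic anhydrase, at 724 ± 159 CPM in db/m and 1634 ± 424 CPM in db/db, Gfi1b, a transcription factor of both lineages, at 52.6 ± 6.08 and 97.5 ± 28.0 CPM, and Epor, the erythropoietin receptor, at 10.9 ± 3.21 and 30.3 ± 15.9 CPM. The camera test called both lists, with adjusted p of 5.28e-13 for megakaryocyte and 1.09e-09 for erythroid genes, and the adjusted p was 0.453 for each with an estimated correlation. Globin genes were not analysed here. The centred erythroid level was highest in db/db replicates 3 (2.36) and 4 (1.05), which share a title prefix, and was 0.13 in db/db replicate 1. In db/db replicate 2 (-0.70) it lay below db/m replicates 1 (-0.51), 3 (-0.26) and 4 (-0.68). With quality weights the erythroid median was 1.22, and with the library of lowest weight in each group left out it was 1.29. When only db/db replicate 3 was left out, the erythroid median was 1.09.

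Most genes of the hematopoietic stem cell (HSC) list had positive log2 fold changes too, 21 of 24 tested, with a median of 0.57. The others were Ly6a, Hoxb4 (-0.29) and Ifitm1 (-0.07). The list levels overlapped between the groups, since db/db replicate 3 (-0.22, centred) lay below db/m replicates 1 (0.11) and 2 (-0.04). Adjusted over the list alone, 9 rose, 1 (Ly6a) fell and 14 did not pass, while over all genes Ly6a alone passed. Robo4, a receptor that retains stem cells in the marrow, went from 23.6 ± 3.98 to 44.6 ± 7.37 CPM, Txnip, an inhibitor of thioredoxin that responds to glucose, from 362 ± 39.0 to 652 ± 146 CPM, and Tal1, a transcription factor required for blood formation, from 26.5 ± 2.79 to 41.1 ± 5.75 CPM. Kit, the other antigen of the sort, was at 658 ± 101 and 812 ± 216 CPM, with an adjusted p of 0.500 by edgeR. Camera called the HSC list with an adjusted p of 1.23e-06, which became an adjusted p of 0.640 with an estimated correlation, and the median was 0.38 without db/m replicate 3. The HSC ageing list had a median of 0.40 and a camera adjusted p of 0.0155 (adjusted p = 0.767 with an estimated correlation). Adjusted over the list alone 3 of its 17 genes rose, Itgb3, Aldh1a1 and Vwf, and 1 fell, the metallothionein Mt1, which binds zinc and copper. This call was lost without db/m replicate 3 (median 0.24) and without db/db replicate 1 (median 0.34).

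**Figure D2:**
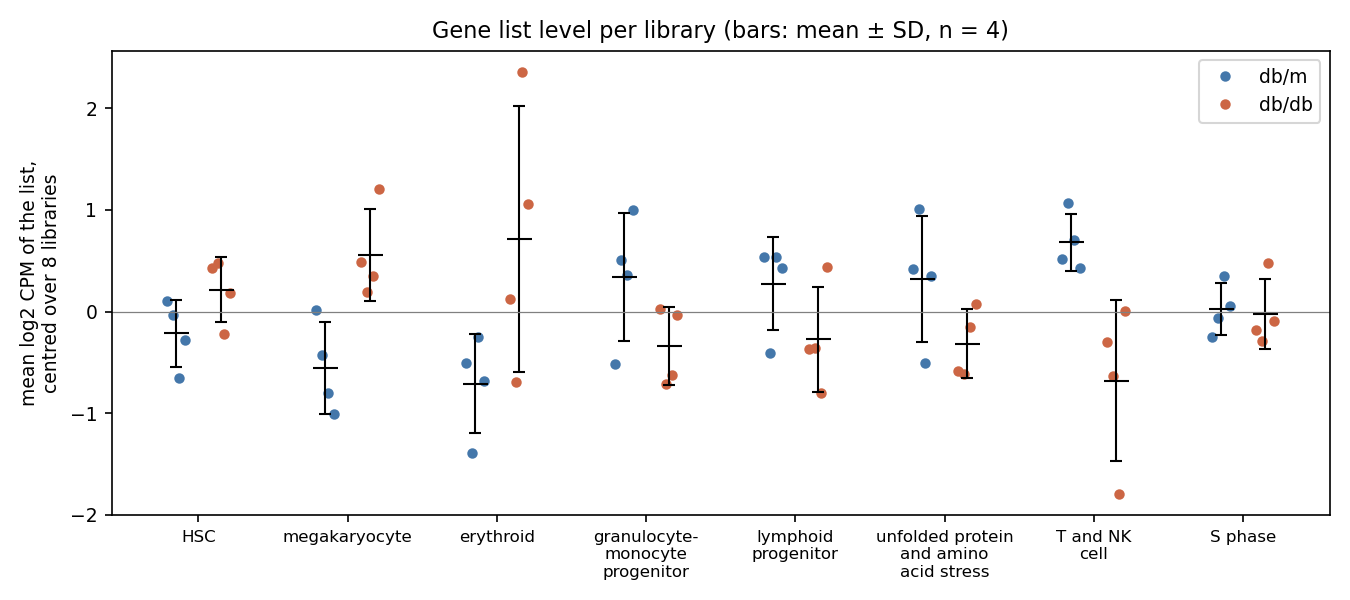
Level of 8 gene lists in each library, as the mean log2 CPM of the list's genes centred over the 8 libraries; points are libraries, and bars give the mean ± SD of 4 libraries per genotype. Megakaryocyte genes lie higher in all 4 db/db libraries, erythroid genes reach 2.36 in db/db replicate 3, and S phase genes overlap.

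Most genes of the myeloid and lymphoid lists were lower in db/db, but the list levels overlapped between the groups. The centred granulocyte-monocyte level of db/m replicate 1 (-0.52) lay below db/db replicates 1 (0.03) and 4 (-0.04). The lymphoid level of db/m replicate 2 (-0.41) lay below db/db replicates 1 (-0.37) and 2 (-0.36), and db/db replicate 4 (0.434) lay above db/m replicate 4 (0.429). In the granulocyte-monocyte progenitor list 17 of 19 genes had negative log2 fold changes, with a median of -0.87, and 6 fell adjusted over the list alone (0 over all genes). Ly6c2, a surface antigen of monocytes and their precursors, went from 614 ± 238 to 131 ± 46.2 CPM, Irf8, a transcription factor of monocytes and dendritic cells, from 386 ± 217 to 124 ± 50.4 CPM, and Csf3r, the receptor of granulocyte colony-stimulating factor, from 296 ± 46.4 to 179 ± 44.4 CPM. In the lymphoid progenitor list 16 of 18 genes were negative, with a median of -0.41, and 7 fell adjusted over the list alone (0 over all genes). Dntt, the polymerase that adds bases at antigen receptor joints, went from 641 ± 185 to 273 ± 83.1 CPM, and Cd52 from 177 ± 53.03 to 57.5 ± 24.1 CPM. Camera adjusted p was 1.54e-07 for the granulocyte-monocyte and 1.97e-06 for the lymphoid list, and the adjusted p was 0.453 for both with an estimated correlation. Without db/m replicate 4 the granulocyte-monocyte median was -0.49, and without db/db replicate 4 the lymphoid median was -0.88. The lymphoid median was -0.17 with the plasma cell covariate and -0.82 with 1 surrogate variable.

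Genes of protein folding and secretion were lower in db/db, and so were genes of plasma cells. In the list of unfolded protein and amino acid stress genes 13 of 20 fell adjusted over the list alone (0 over all genes), with a median of -0.95. Xbp1, the transcription factor of the unfolded protein response, went from 1214 ± 413 to 409 ± 149 CPM, Edem1, which helps remove misfolded glycoproteins, from 552 ± 146 to 190 ± 71.1 CPM, and Pdia4, a disulfide isomerase, from 831 ± 385 to 285 ± 82.2 CPM. The 7 that did not pass include the chaperone Hspa5 (log2 fold change 0.29) and the transcription factor Atf4 (0.09). Camera adjusted p was 1.09e-09 (adjusted p = 0.453 with an estimated correlation). The levels of this list overlapped between the groups: db/m replicate 3 (-0.51, centred) lay below db/db replicates 3 (-0.15) and 4 (0.08). A plasma cell list of 16 genes, chosen after the data were seen, had a median of -1.85, with all 16 past the threshold adjusted over the list alone (0 over all genes), a count that its choice after the result makes no independent evidence. Immunoglobulin genes were not analysed here. Without the 3 db/m libraries of high intergenic share, which leaves db/m replicate 3 as the only db/m library, its median was -0.49. Jchain, the joining chain of secreted immunoglobulin, was at 10942 ± 5435 CPM in db/m and 2992 ± 2168 CPM in db/db. The 3 db/m libraries of high intergenic share, replicates 1, 2 and 4, had 14258, 15186 and 11100 CPM of it. Every other library had 5172 CPM or less, so leaving out these 3 also removes the libraries with the most Jchain. With the mean level of these 16 genes as a covariate the median of the stress list was -0.02 and its call was lost. That outcome was largely set beforehand, because the genes were chosen after the gene table was seen, some belong to the secretory pathway, and their level nearly follows genotype (centred level 0.86 to 1.34 in 3 db/m libraries and -0.06 in db/m replicate 3, against -1.53 to -0.51 in 3 db/db libraries and -0.00468 in db/db replicate 4).

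**Figure D3:**
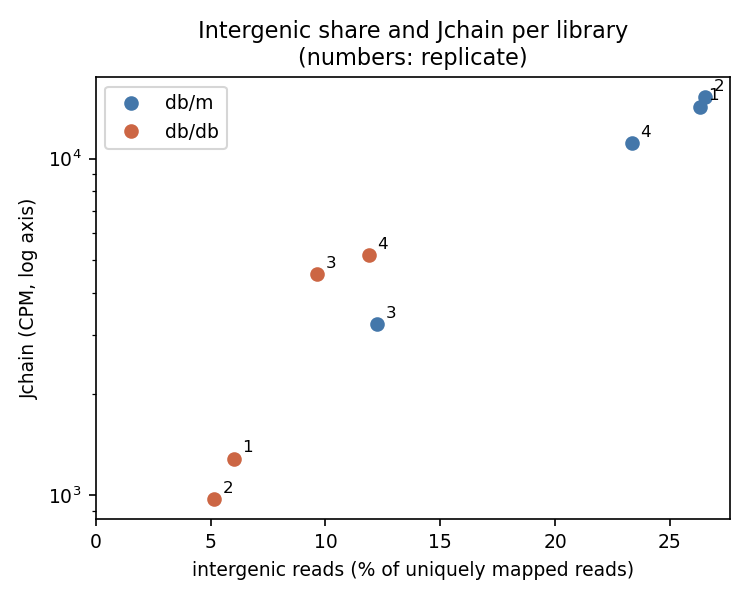
Jchain level (CPM, log axis) against the share of uniquely mapped reads in intergenic sequence (%, linear axis) for the 8 libraries, numbered by replicate. Db/m replicates 1, 2 and 4 lie at 26.3%, 26.5% and 23.4%, and the other 5 libraries at 12.2% or less.

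Markers of other cell types that the sort could carry were also measured. The T and NK cell list was lower, with a median of -1.56 and 7 of 12 genes that fell adjusted over the list alone. Among them were Cd3g, at 3.59 ± 1.34 CPM in db/m and 0.720 ± 0.346 CPM in db/db, and Lck, at 74.2 ± 2.44 and 54.7 ± 8.21 CPM. Some members thus lay near the detection limit. With the stricter filter of at least 1 CPM in 4 libraries the list was still called, with a median of -1.04. Lower calls were also made for B cell genes (median -0.92, 1 of 8 fell adjusted over the list alone), dendritic cell genes (median -0.34, 3 of 11 fell) and eosinophil and ILC2 genes (median -0.62, 2 of 11 fell). Stroma and adipocyte genes were called higher (median 1.29, 0 of 12 passed adjusted over the list alone). Camera adjusted p for these 5 lists was 1.54e-07, 0.000596, 0.0171, 0.0464 and 0.0175 in that order. With an estimated correlation the adjusted p was 0.453 for T and NK, B and dendritic cells, 0.710 for eosinophils and 0.767 for stroma. The eosinophil and ILC2 call was lost without any 1 of 6 libraries (medians -0.87 to -0.47, all but db/m replicate 3 and db/db replicate 4), the stroma call without db/m replicate 2 (1.00), db/m replicate 3 (0.99) or db/db replicate 4 (0.64), and the dendritic cell call without db/db replicate 1 (-0.27) or 3 (-0.28). The B cell median was -1.59 without db/db replicate 4 and the call was lost without the 3 db/m libraries of high intergenic share (-0.23). The monocyte and macrophage list had a median of 1.11 and an adjusted p of 0.0678, and without db/db replicate 3 it was called with a median of 1.502. Its median was 0.39 with limma-voom and -0.11 with 1 surrogate variable, and it was called in neither. Lists of neutrophil (median -0.30), mast cell and basophil (-0.73) and endothelial genes (0.31) were not called, with camera adjusted p of 0.109, 0.491 and 0.287. Neutrophil genes were called lower without db/m replicate 3 (-0.58) or db/db replicate 4 (-1.81), and mast cell genes without db/m replicate 3 (-1.01). With the plasma cell covariate the direction turned for neutrophil (2.16), mast cell (0.95) and eosinophil and ILC2 genes (1.46), all called higher, and for B cell genes (0.62), not called.

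Among lists of cell function, 3 more were called. Nuclear genes of oxidative phosphorylation were lower by a small amount, 81 of 83 with negative log2 fold changes and a median of -0.18, and 0 passed adjusted over the list alone (camera adjusted p = 2.35e-07, adjusted p = 0.767 with an estimated correlation). With the plasma cell covariate the median was -0.08 and the call was lost (adjusted p = 0.129), and the median was -0.11 without db/m replicate 4 and -0.28 without db/db replicate 3. Antigen presentation genes had a median of -0.14, and 1 of 17, the immunoproteasome subunit Psmb8, fell adjusted over the list alone (camera adjusted p = 0.0380, adjusted p = 0.767 with an estimated correlation). Immediate early and dissociation genes were higher, with a median of 0.34 and 0 of 24 past the threshold adjusted over the list alone (camera adjusted p = 0.00910, adjusted p = 0.796 with an estimated correlation). The median of this last list was 1.86 with the plasma cell covariate and 2.00 with db/m replicate 3 as the only db/m library, and it was called in both. It was not called with quality weights (0.19) or with the library of lowest weight in each group left out, where the direction turned (-0.20). Its call ended without db/m replicate 3 (median 0.19) and without db/db replicate 3 (median 0.05), and the antigen presentation call ended without db/m replicate 1 (-0.06), db/m replicate 2 (-0.12) or db/db replicate 3 (-0.06), while its median was -0.24 without db/m replicate 3. The antigen presentation call also ended with quality weights (-0.08, adjusted p = 0.0757), the plasma cell covariate (-0.12, adjusted p = 0.3002) and 3 libraries against 3 (-0.11, adjusted p = 0.0777), and the median turned to 0.058 with db/m replicate 3 as the only db/m library.

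Cell cycle, clock and the remaining metabolic lists were not called with all 8 libraries and the test fixed in advance. Median log2 fold changes were -0.05 for S phase, -0.22 for G2 and M phase, -0.01 for the circadian clock, 0.02 for insulin, IGF and leptin signalling, -0.08 for glycolysis, 0.01 for fatty acid oxidation and -0.04 for cholesterol and fatty acid synthesis. They were 0.07 for antioxidant, -0.14 for p53 target, -0.14 for interferon response, -0.10 for NF-kB and inflammation, -0.04 for homing and adhesion, 0.34 for angiogenic, 0.00 for chromatin, 0.06 for autophagy and lysosome and -0.06 for ribosomal protein genes. Several of these were called in other fits. G2 and M phase genes were called lower with the likelihood ratio test (-0.22), with the plasma cell covariate (-0.58), without the 3 db/m libraries of high intergenic share (-0.71), and without db/m replicate 1 (-0.34), db/m replicate 2 (-0.37) or db/db replicate 3 (-0.37). S phase genes were called lower without those 3 db/m libraries (-0.38) and without db/db replicate 3 (-0.23). Leaving out 1 library also gave calls for interferon response (db/m replicate 2, -0.26, db/m replicate 4, -0.22, or db/db replicate 2, -0.22), ribosomal protein (db/m replicate 1, -0.10, db/m replicate 3, -0.10, or db/db replicate 3, -0.18), NF-kB (db/m replicate 3, -0.33, lower), angiogenic (db/m replicate 1, 0.61) and cholesterol genes (db/db replicate 3, -0.12). NF-kB genes were also called lower with the library of lowest weight in each group left out (-0.62), but higher with the plasma cell covariate (1.15) and with db/m replicate 3 as the only db/m library (1.61), which had the lowest NF-kB level of the 8 libraries. Clock genes were called higher in the same fits (0.46 and 0.49), as were p53 target (0.13) and homing genes (0.065) in the second. The p53 target list had a mean of 0.01, opposite in sign to its median. Single members passed adjusted over the list alone in some of them: the integrin Itgal fell (log2 fold change -1.34 ± 0.23), the antiviral genes Bst2 (-0.80 ± 0.14) and Zbp1 (-0.97 ± 0.20) fell, Trp53inp1 fell (-1.01 ± 0.21), Ptpn1, a phosphatase of the insulin and leptin receptors, fell (-0.37 ± 0.10), and Pik3r1, a regulatory subunit of PI3 kinase, rose (0.64 ± 0.17). In all, camera called 15 of 36 lists, 6 higher and 9 lower, and with an estimated correlation it called 0, the smallest adjusted p being 0.453. Fry called 0 lists in one direction (smallest adjusted p = 0.182) and 12 for change in either direction.

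Lepr itself, the gene that carries the mutation (mm10 chromosome 4, 101717407 to 101815354), was near the detection limit, at 0.671 ± 0.481 CPM in db/m and 1.20 ± 0.995 CPM in db/db, with an adjusted p of 0.662 by edgeR. The counts are per gene and do not separate its isoforms. Of 84 tested genes within 10 Mb of Lepr 0 were called, against 5 of 13624 elsewhere (two-sided Fisher's exact test, p = 1). So few calls in all made this outcome nearly certain, so it says little about the DNA near Lepr. At an unadjusted p under 0.05 the shares were 20.2% and 15.3% (two-sided Fisher's exact test, p = 0.223), and with the likelihood ratio test 5 of the 84 were called (p = 0.411). All 4 tested Y-linked genes were expressed in both groups, Ddx3y at 87.1 ± 23.3 CPM in db/m and 107 ± 15.8 CPM in db/db, and the sex-linked list was not called (median 0.35, camera adjusted p = 0.0995), except without db/m replicate 1 (0.45).

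The 6 library measures fixed in advance did not separate the groups by two-sided exact permutation tests over 70 assignments. Reads assigned to genes made up 72.3% ± 6.68 of uniquely mapped reads in db/m and 83.3% ± 3.60 in db/db (SD, n = 4 each, exact p = 0.0571, adjusted p = 0.257), and without db/m replicate 3 this measure passed the unadjusted threshold. Exact p was 0.486 for total gene counts, 0.171 for the uniquely mapped share, 0.171 for detected genes, 0.943 for the share of the 10 most abundant genes and 0.0857 for the mitochondrial share. Of 4 further measures chosen after the data were seen, the intergenic share was 22.1% ± 6.74 in db/m and 8.18% ± 3.15 in db/db (exact p = 0.0286, the smallest that 4 against 4 allows, adjusted p = 0.114). Intronic reads made up 6.24% ± 1.71 and 9.44% ± 1.31 (exact p = 0.0571), and the rRNA share and RNA integrity number had exact p of 0.771 and 1.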

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

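In 202 groups of 4 libraries examined, chance places about 1 in 20 with a library far from the other 3, and 10 were found. Db/m replicate 3 stood apart from the other db/m libraries in 5 of them. It had 145 CPM of Ly6d against 320 to 333, 1545 CPM of Ly6e against 1837 to 1873, 179 CPM of Sec11c against 277 to 296 and 247 CPM of Dusp2 against 497 to 540. Its uniquely mapped share was 90.4% against 87.6% to 88.1%. Db/db replicate 4 had 110 CPM of Cd79b against 51.0 to 60.8 in the other db/db libraries and 1203 CPM of Ly6e against 979 to 1003. Db/m replicate 2 had 4.53 CPM of Zan against 5.01 to 5.06, and its centred level of the lymphoid progenitor list was -0.41 against 0.43 to 0.54. Db/db replicate 3 had 5.71% of its counts in the 10 most abundant genes against 3.94% to 4.21%.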

How the results depend on the processing

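The likelihood ratio test, the plasma cell covariate and both sets of omitted libraries were chosen after seeing the data, and the covariate nearly follows genotype. The count of 5 genes stayed at 5 with RLE scaling, no filter and the stricter filter, which kept the same genes. It was 0 with upper-quartile scaling, 0 with limma-voom, 192 with quality weights, 14 with the title prefix as a correlated block, 3 with 1 surrogate variable, 767 with DESeq2 (1070 genes without an adjusted p), 587 with the likelihood ratio test, 2 with the plasma cell covariate and 195 with the library of lowest weight in each group left out. Leaving out 1 library at a time gave 0 to 90. Without the 3 db/m libraries of high intergenic share none of these calls was kept. The log2 fold changes there were 1.37 for Pde3b, 1.38 for Klhl4, -0.69 for Cnp, -1.28 for Ly6a and -0.94 for Ckap4. The lone db/m library left there, replicate 3, has the lowest weight of the db/m libraries (0.509), so what moves in that fit may be that library's own level. The 3 libraries left out also had the highest Jchain of all, so that fit does not separate intergenic share from plasma cell RNA. On simulated counts with 200 changed genes DESeq2 made 208 calls and the likelihood ratio test 196, against 146 for the quasi-likelihood test. False calls were 23.1% and 20.4% for the first 2, a share that need not hold in the real data. The cause of these changes in the gene count was not tested. Of the 36 lists, 0 were called with an estimated correlation and 0 by fry in one direction, and 12 to 20 in other settings with list tests (DESeq2 had none), which called 10 to 15 of the original 15, 1 of them (eosinophils, with the covariate) in the opposite direction. Megakaryocyte, erythroid, HSC, granulocyte-monocyte, lymphoid and T and NK lists were called in each of those settings, all with the preset of 0.01. Apart from single omitted libraries, calls were lost for HSC ageing (1 surrogate variable, 3 against 3), immediate early genes (quality weights), stroma (limma-voom, quality weights, prefix block), eosinophils (RLE, limma-voom, prefix block, 1 surrogate variable), dendritic cells (covariate, 3 against 3, without the 3 db/m libraries) and stress genes (without the 3 db/m libraries). They were gained for interferon (1 surrogate variable, covariate, without the 3 db/m libraries), angiogenic (covariate, without the 3 db/m libraries), ribosomal (limma-voom, quality weights, 3 against 3), NF-kB and mast cell (3 against 3), neutrophil (limma-voom, 1 surrogate variable), macrophage (quality weights, likelihood ratio test, 3 against 3) and autophagy genes (without the 3 db/m libraries). Counting lists called before or after, medians reversed with the plasma cell covariate to 1.15 for NF-kB, 0.46 for the clock, 2.16 for neutrophils, 0.95 for mast cells and 1.46 for eosinophils, all called higher there, and to 0.62 for B cells, not called. Without the 3 db/m libraries they reversed to 0.13 for p53 targets, 1.61 for NF-kB, 0.49 for the clock, 0.065 for homing and 1.07 for mast cells, all called higher, and to 0.058 for antigen presentation and 0.94 for eosinophils, not called. With 3 against 3 immediate early genes reversed to -0.20, not called. Some uncalled lists changed sign too, such as homing (0.069) and ribosomal genes (0.089) with the covariate. Among kept calls, the covariate gave medians of 2.19 for megakaryocyte, 0.93 for HSC ageing and 2.55 for stroma genes, and omitting the 3 db/m libraries gave 1.10 for HSC, 1.12 for HSC ageing and 2.14 for stroma genes. Near Lepr Fisher's test passed in no setting, with 5 genes called in the window by DESeq2, 5 by the likelihood ratio test and 1 with 3 against 3. The count of library measures went from 0 to a range of 0 to 1 when 1 library was left out. No paired analysis was possible because the suffix numbers of the titles repeat under different prefixes within a genotype and name no shared animal.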

Other observations

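The tests of plasma cell genes, of dilution and of db/db replicate 3 were chosen after the result was seen. Within 2 Mb of Ly6a on chromosome 15, 8 genes of the Ly6 family were tested, Ly6a among them. All 8 were lower in db/db at an unadjusted p under 0.05. They include Ly6d, at 282 ± 91.4 CPM in db/m and 73.5 ± 60.5 CPM in db/db, and Ly6e, at 1777 ± 155 and 1047 ± 105 CPM, with adjusted p of 0.123 and 0.0797 by edgeR. Members of the family may share reads, so the 8 are not independent of each other.

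Of the 35 ways to split the 8 libraries 4 against 4, only the real split gave as many as 5 genes (1 of 35), and the highest other gave 2. Chance can be excluded for the gene count only if the libraries are otherwise alike, because the real split alone keeps each of the 4 title prefixes in 1 group, so prefix and genotype cannot be told apart. With the prefix as a block the count was 14, at an estimated block correlation of -0.0419. Because each prefix lies in 1 genotype, the block cannot take out a difference between prefixes, so the 14 does not bear on it. Of the 8 fits without 1 library 5 gave 0, where Ly6a still had log2 fold changes of -1.87 to -1.70. With the likelihood ratio test 1 of 35 splits, the real one, reached 587 genes, with 389 in the highest other. For the lists chance cannot be excluded, because 19 of the 35 splits gave at least the real 15 calls and the highest other gave 23. The median of the other splits was 15. All these counts used the preset correlation of 0.01. Estimated correlations were 0.52 for megakaryocyte, 0.82 for erythroid, 0.57 for HSC, 0.37 for granulocyte-monocyte, 0.27 for lymphoid and 0.35 for T and NK genes. Calls kept across settings at that preset, and their small p-values, are therefore no evidence against chance.

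Plasma cell and secretory genes were lower in db/db, and Jchain ranged from 977 CPM in db/db replicate 2 to 15186 CPM in db/m replicate 2. An unfolded protein response in the LSK cells stays open: 7 plasma cell identity genes had a median log2 fold change of -1.88, but they were chosen after the gene table was seen, so this value excludes nothing. Plasma cell RNA in varying amount may account for the pattern. The other 15 markers followed Jchain within groups with a median correlation of 0.931, above the 95th percentile of 0.279 of 10000 random lists of matched expression. That value cannot separate the 2 explanations, because the random lists hold unrelated genes and any set of genes that varies together would pass. The c-Kit gate would normally remove plasma cells, and a genotype difference in their number stays open as untested.

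Ly6a was lower in every db/db library than in any db/m library. Of 66 tested genes within 2 Mb, Ly6 family left out, 6.06% had an unadjusted p under 0.05, against 15.3% elsewhere. The neighbours thus showed no excess of differing genes. A regional difference that alters few of the neighbours could give the same share, so the value cannot exclude one. That share left out the cluster's own genes, of which 8 of 8, Ly6a among them, were lower. A difference confined to the Ly6 cluster therefore stays open too. Plasma cell RNA could carry part of it: with the plasma cell level as a covariate the log2 fold change went from -1.83 ± 0.24 to -1.17 ± 0.34 (SE), with an adjusted p of 0.397. The covariate nearly follows genotype, which leaves open how much remains.

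Megakaryocyte and erythroid genes were higher in db/db. Less dilution by plasma cell RNA would raise genes of all progenitors alike, but the S phase list had a median log2 fold change of -0.052 (quartiles -0.12 and 0.00), against 1.29 for megakaryocyte genes. TMM scaling takes out a shift shared by most genes (median of all genes 0.0094), so a flat S phase value alone shows nothing. Scaling moves both lists by the same amount, so only the gap between them bears on dilution. Erythroid cells in db/db replicate 3 may carry part of the erythroid difference, although lineage depletion and the Sca-1 gate would normally remove them. The erythroid median was 2.03 with that library and 1.09 without it, while the megakaryocyte median was 1.36 without it. Replicate 4 of db/db, which has the same title prefix, also had a high centred erythroid level (1.05). Whether diabetes shifts the make-up of the LSK gate stays open as a hypothesis that was not tested.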
